A study of Mus musculus with 12 samples.

How the data were processed

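Single-cell RNA sequencing of full-thickness dorsal skin was analysed in 12 samples from C57BL/6 mice, 6 taken in the growth phase of the hair cycle (anagen, 5 weeks of age) and 6 in its resting phase (telogen, 9 weeks of age). Per the labels, the mice were female, and the skin was digested with collagenase and then trypsin before the stromal and epidermal suspensions were pooled. The samples form a main dataset, made with version 1 of the Chromium 3' kit and sequenced on a HiSeq2500, and a validation dataset, made with version 3 and sequenced on a NovaSeq instrument. Each dataset held 3 anagen and 3 telogen replicates. Per the labels, cells of validation telogen replicates 2 and 3 came from the same animal, so these were summed and the validation comparison was of 3 anagen against 2 telogen animals. The design text says that a telogen replicate of the main dataset was removed by the authors in retrospect, and the labels give 2 telogen mice for their final dataset, without naming the replicate. All 3 were kept here. Beyond these statements nothing is known of how independent the replicates are. The p-values of single genes and of shares thus measure the spread between these samples, part of which may be technical.

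The deposited values are UMI counts per gene and barcode, not normalised. Per the submitters' processing notes the counts were made with Cell Ranger, of which versions 1.1.0, 1.2.1 and 3.0.2 are named without their roles, on genome build mm10. The annotation release and the cell-calling settings are not given in the sources used here. The main dataset was deposited as a count matrix per stage with a list assigning barcodes to replicates, and how the authors assigned them is not stated. Of the main barcodes, 3325 anagen and 2826 telogen ones belonged to a single replicate. The 148 telogen barcodes listed as unassigned, and 6 anagen and 30 telogen barcodes listed under 2 replicates, were not used. The validation dataset was deposited as a count matrix per library.

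In the validation dataset 2367 barcode sequences occurred in more than 1 library and 218 in all 6. Their largest UMI total was a median of 25.1 times the next largest. Such a sequence was kept only in the library with the largest total, where that total was at least 8 times the next, and the other 5566 of 17037 barcodes (32.7%) were left out as copies. This step was added after the shared barcodes were seen. Cells then needed at least 500 detected genes in the validation dataset or 300 in the main dataset, and at most 10% mitochondrial UMIs. The list of assigned barcodes held every main barcode and so was no cell filter of its own. Doublets were called per library with Scrublet through scanpy 1.11.5 and removed. They were 36 of 6092 main cells (0.591%) and 98 of 6794 validation cells (1.44%), which left 6056 and 6696 cells.

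Cells of each dataset were clustered on 2000 variable genes, 40 components and 15 neighbours with the Leiden method at resolution 1.5 (leidenalg 0.10.2, igraph 0.11.9). Clusters were named from marker lists of 22 cell classes. The markers were fixed before the data were examined, and so were the tests, thresholds, gene lists and most alternatives. The rule that turns markers into a name was chosen after the clusters were seen, and clusters that failed it stayed unnamed. Names here are rebuilt and may differ from those of the authors.

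Counts were summed per animal (validation) or library (main) over the cells of a class. Stages were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, edgeR's filter on low counts and Benjamini-Hochberg adjustment within the class. The threshold was an adjusted p of 0.05, and log2 differences are anagen minus telogen throughout, with a standard error (SE) from the same fit. A class needed at least 20 cells in every animal. Fibroblasts and differentiated keratinocytes of the validation dataset fell under that in an anagen animal and were tested with at least 10 cells. Main telogen replicate 3 had too few cells for 4 classes, which were tested in the other 5 libraries, macrophages with at least 10 cells. Both changes were made after the cell numbers were seen. Vascular endothelial cells were planned as a class too. A test of 2 against 2 main libraries with at least 10 cells was tried on 860 genes and was left out of the report. There edgeR called 0 genes, 109 had an unadjusted p under 0.05, and DESeq2 called 6. In the validation dataset an animal had 1 to 14 of these cells, and no test was made.

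Shares of cells were compared with a two-sided exact permutation test within each dataset, where the smallest possible p is 0.1, and with an exact permutation stratified by dataset. That test had 200 assignments, not the 100 planned, because the telogen libraries of the main dataset could be told apart, and its smallest possible p is 0.005. Shares were adjusted over 17 classes. Gene lists, 21 in number, were compared with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over all pairs of class and list in a dataset. At the preset correlation camera compares the genes of a list with the other genes. Its p-value thus does not measure how a list as a whole varies between animals. Camera with an estimated correlation and fry were run beside it. The list tests of the main dataset were added after the data were seen. A list count is given over all genes tested and adjusted over the list alone. Means are given with the SD over animals or libraries, and CPM values are the summed counts scaled to a common library total.

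Genes named in the text follow a fixed rule. In each class tested in the validation dataset they were up to 10 rising and 10 falling genes with the largest log2 difference among those past the threshold. Each needed a mean of at least 20 CPM in the higher stage, at least the level of all kept cells of the same libraries, no overlap between stages, and the same sign in the main dataset where measured. Predicted, ribosomal and mitochondrial genes and the markers of the class were left out. Up to 5 called members of each list and class are named as examples. A gene named by this rule with 0 UMIs in a validation stage is given as a lower bound against 3 UMIs over that group, and with 1 to 3 UMIs only the levels are given. Other genes with 0 UMIs in a stage are given by their levels. Positions are those of GENCODE M21 on GRCm38. Reads of close paralogs could have been split in counting, which leaves Stfa1, Stfa3, Ccl27b, Skint3, Hba-a1, Hba-a2, Krt14 and Pgk1 uncertain.

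The test was tested on simulated data drawn from the real means and library sizes. Genes were drawn independently, with the same dispersion for every gene of a class. For validation basal keratinocytes edgeR found 68% of genes changed 2-fold and 99% of those changed 4-fold, with 4.02% false calls, over 10601 genes. The shares were 14.1% and 80% for validation macrophages, 12.2% and 69.7% for validation fibroblasts, 17.2% and 88.4% for main differentiated keratinocytes, and 16.5% and 80.8% for main fibroblasts. In these simulations a change of 2-fold in the smaller classes was therefore mostly below detection. Real genes differ in dispersion and are correlated, so the shares found and the false calls may differ in the real data.

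Alternatives were DESeq2 1.42.0 and its size factors, no filter on low counts, telogen replicates 2 and 3 apart, a replicate block, both datasets in the same fit, doublets kept, a stricter cell filter (5% mitochondrial UMIs, 1000 genes), resolution 0.8, clusters made without called genes, animals thinned to equal cell numbers, only genes at or above the level of all cells, shares within epithelial or within stromal and immune cells, and leaving out each replicate. Added after the data were seen were barcode copies kept, the presence of Xist as a covariate, leaving out the 2 libraries without Xist, clusters held by both stages alone, leaving out a cluster led by Fosl1 or Pi16, and shares of the cells outside the anagen hair lineage. In both Xist settings the stage difference rests on anagen replicate 1, the only validation anagen animal with Xist, against the telogen animals. They are thus nearly the same contrast and not separate checks. The minimum of 10 cells, the tests without 1 main library and camera on the main dataset were also added then. Calculations used numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The results of 1 gene are not reported.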

Results

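Cells from full-thickness dorsal skin of mice in anagen (5w) and telogen (9w) were profiled with droplet-based single-cell RNA sequencing, in which each UMI marks a captured transcript molecule. The main dataset kept 1479, 1156 and 657 cells of anagen replicates 1 to 3, with 7249032, 5004729 and 2129950 UMIs, and 1174, 1364 and 226 cells of telogen replicates 1 to 3, with 2529658, 2202173 and 203837 UMIs. The median UMI count per kept main cell was 3952, 3507 and 2756 at anagen and 1682, 1309 and 829 at telogen. The validation dataset was deeper. It kept 697, 1043 and 1917 cells of the anagen replicates, with 26679622, 30160310 and 56006744 UMIs, and 823, 1452 and 764 cells of the telogen replicates, with 14673980, 20608844 and 13244162 UMIs. The medians per kept validation cell were 33923, 24372 and 25138 UMIs at anagen and 18171, 14295 and 17543 at telogen. Depth thus differed between stages in both datasets. The lowest UMI total of a main barcode listed under a single replicate was 1310, 1313 and 1308 at anagen and 837, 587 and 587 at telogen. The deposited main cells thus reached lower totals at telogen, and what this does to the main shares was not tested. Xist, the RNA of the inactive X chromosome in females, was at 773 CPM in validation anagen replicate 1 but at 0.199 and 0.089 CPM in anagen replicates 2 and 3, against 1155 to 1317 CPM in the validation telogen libraries and 464 to 719 CPM in the main dataset. The Y-linked Ddx3y, at 39.5 and 40.4 CPM in validation anagen replicates 2 and 3, had 0 counts in the other 10 libraries. The labels give all mice as female.

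The first comparison asked which cell classes made up the suspension in each stage. The anagen hair lineage, which joined clusters led by hair shaft and inner root sheath genes such as Krt35 and Krt71 with clusters led by cell cycle genes such as Ube2c and Stmn1, made up 37.8% ± 4.86 (SD, n = 3) of validation cells at anagen and 1 of 3039 cells at telogen. Of main cells it made up 37.2% ± 6.03 (n = 3) at anagen and 0 of 2764 cells at telogen, which allows a share of up to 0.109% for cells in clusters of that name. Unnamed clusters are not in these shares. A main one with Krt28 and Krt25 among its leading genes held 397 anagen and 10 telogen cells, the latter all of telogen replicate 2. A validation one led by Hbb-bs, Fabp5 and Stmn1 held 450 anagen and 0 telogen cells. The largest main cluster of the class (40.6% of it, led by Ube2c, Stmn1 and Rrm2) and 3 of the 9 validation clusters (17.9%, 12.8% and 7.97%) had no marker of the class among their leading genes. Differentiated keratinocytes, the suprabasal cells that carry Krt1 and Krt10, held a lower share at anagen, 3.52% ± 1.71 against 9.67% ± 1.1 (n = 2) in the validation dataset and 5.27% ± 0.823 against 31.9% ± 20.7 (n = 3) in the main dataset. The dermal papilla and dermal sheath, the mesenchyme of the follicle, also held a lower share at anagen, 0.892% ± 0.278 against 2.40% ± 0.209 and 0.0288% ± 0.0499 (1 cell) against 0.936% ± 0.428. For these 3 of 17 classes every anagen sample lay on the same side of every telogen sample in both datasets, with an exact stratified two-sided permutation p of 0.005, the smallest possible, and an adjusted p of 0.0283. The mean differences were 37.5, -16.4 and -1.21 percentage points, and that of differentiated keratinocytes was -10.4 without main telogen replicate 3. The shares of a sample sum to a fixed total, so the hair lineage share at anagen lowers every other share there. Part of the lower shares of differentiated keratinocytes and dermal papilla follows from that. Neither difference turned sign among the cells outside the hair lineage. With cells clustered without the genes called between stages, the hair lineage difference was 51.1 percentage points (exact permutation, adjusted p = 0.0213). With barcode copies kept it was 22.8 percentage points with an adjusted p of 0.128, and no class passed. With main telogen replicate 3 left out 7 classes passed, with validation telogen replicate 2 left out 4 passed, and with any of the other libraries except validation telogen replicate 3 left out none passed, in tests with fewer assignments.

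The remaining classes did not pass. Basal keratinocytes, which line the basement membrane and carry Krt5 and Krt14, were 11.1% ± 4.99 of validation cells at anagen against 34.1% ± 0.461 at telogen, and 14.7% ± 2.39 against 16.5% ± 15.9 in the main dataset (exact permutation, adjusted p = 0.243). Bulge and outer root sheath cells, the class that holds follicle stem cells, were 6.38% ± 1.77 against 13.5% ± 7.80 and 5.14% ± 0.720 against 7.86% ± 3.49 (adjusted p = 0.153, permutation). Fibroblasts were 3.06% ± 3.56 against 7.90% ± 5.49 and 2.78% ± 1.03 against 6.14% ± 6.05 (adjusted p = 0.302, permutation). Macrophages and dendritic cells were 4.75% ± 3.34 against 4.49% ± 3.28 and 2.10% ± 1.88 against 3.69% ± 2.27 (adjusted p = 0.7, permutation). T and innate lymphoid cells were 4.33% ± 2.47 against 3.62% ± 0.206 and 1.14% ± 0.641 against 1.03% ± 0.963 (adjusted p = 0.7, permutation). Vascular endothelial cells were 0.498% ± 0.307 against 0.559% ± 0.103 and 0.796% ± 0.141 against 2.94% ± 2.77 (adjusted p = 0.523, permutation). Langerhans cells, the epidermal antigen-presenting cells, were 0.316% ± 0.274 against 0.757% ± 0.304 and 0.403% ± 0.0881 against 1.07% ± 0.755 (adjusted p = 0.085, permutation). Sebocytes, the lipid-secreting gland cells, were 0.577% ± 0.429 against 7.69% ± 11.7 of main cells (adjusted p = 0.34, permutation). No validation cluster was named for sebocytes in either stage, so the validation dataset gives no share of them. Main telogen replicate 3, of 226 cells, held 55.8% differentiated keratinocytes, 21.2% sebocytes and 0.885% basal keratinocytes. Unnamed clusters held 21.5% ± 3.62 of validation cells at anagen and 15.9% ± 2.06 at telogen, and 24.2% ± 7.37 and 15.6% ± 3.58 of main cells. A main one led by Gjb2, with the bulge marker Tbx1, held 281 anagen and 2 telogen cells. A similar validation one led by Gjb2 held 136 and 0. Clusters led by Sostdc1 held 63 and 443 main cells, with Krt14 and Krt5, and 139 and 249 validation cells. Another naming of these could change the direction of the bulge and basal shares. All shares are of captured cells.

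**Figure D1:**
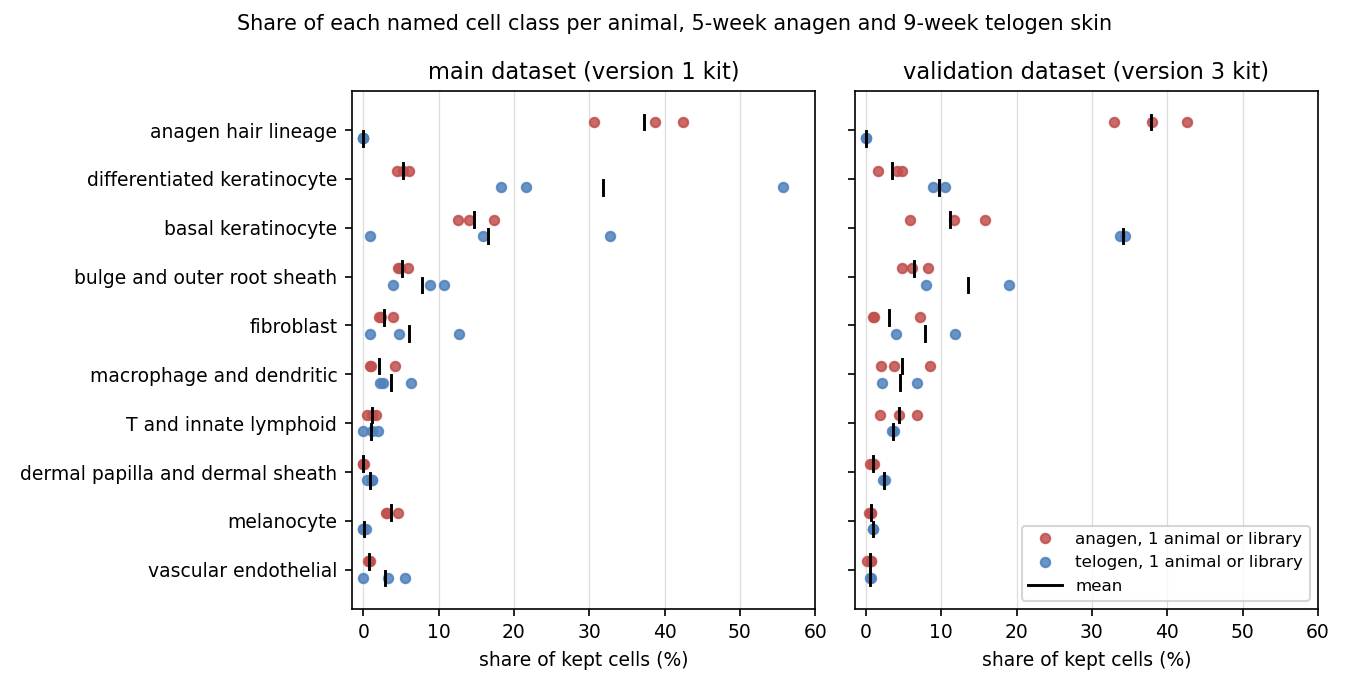
Share of kept cells (%, horizontal axis) in 10 named cell classes, for each animal or library of the main dataset (left) and the validation dataset (right), with anagen in red, telogen in blue and the mean as a black line. The hair lineage lies at 30.6% or more in every anagen sample and at 0.0451% or less in every telogen sample.

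Basal keratinocytes were compared next. In the validation dataset (3 anagen against 2 telogen animals, 1027627 to 13966142 UMIs each) Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factors, rose from 7.94 ± 0.819 CPM at telogen to 37.1 ± 6.66 CPM at anagen (log2 difference 2.21 ± 0.20 SE, adjusted p = 0.0028 by edgeR). Slc16a3, a lactate exporter, rose by 1.74 ± 0.21 (40.4 against 12.7 CPM, adjusted p = 0.0074), and Pgk1, a glycolytic enzyme, by 1.28 ± 0.17 (264 ± 40.2 against 110 ± 4.73 CPM, adjusted p = 0.0085). Ch25h, which hydroxylates cholesterol, fell by 2.68 on the log2 scale (SE 0.39, 9.10 against 40.6 CPM, adjusted p = 0.0112), and Dbp, a transcription factor of the circadian clock output, fell by 2.55 (SE 0.28, 10.5 against 54.0 CPM, adjusted p = 0.0055). Pde4b, a cAMP phosphodiesterase, went from 119 ± 48.8 CPM at telogen to 21.0 ± 4.51 CPM at anagen (log2 difference -2.47 ± 0.27, adjusted p = 0.0048). The other rising genes named by the rule were Stfa3 and Alox12e (3.72 and 2.75), Fam71a, the protease gene Klk8, the basement membrane collagen gene Col18a1, Fam162a and Acp5, between 1.73 for Fam71a and 1.14 for Acp5. Without anagen replicate 3 Fam71a was 1.00 and did not pass. Alox12e had a log2 difference of -1.80 with clustering without called genes and of -0.20 in thinned cells. The other falling genes were Lncpint, the neuropeptide Y receptor gene Npy1r, the Wnt enhancer Rspo3, the stress-induced Gadd45b, Slc25a25, Dennd2c and Gpr146, between -2.47 for Lncpint and -1.65 for Gpr146. They came from 25 rising and 146 falling genes that met the rule. Egln3 (ENSMUSG00000035105) lies on chromosome 12 at 54178981 to 54203860, Pgk1 on the X chromosome at 106187100 to 106203699, Ch25h on chromosome 19 at 34473778 to 34475164, Dbp on chromosome 7 at 45705088 to 45710203 and Pde4b on chromosome 4 at 102087543 to 102607259.

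**Figure D2:**
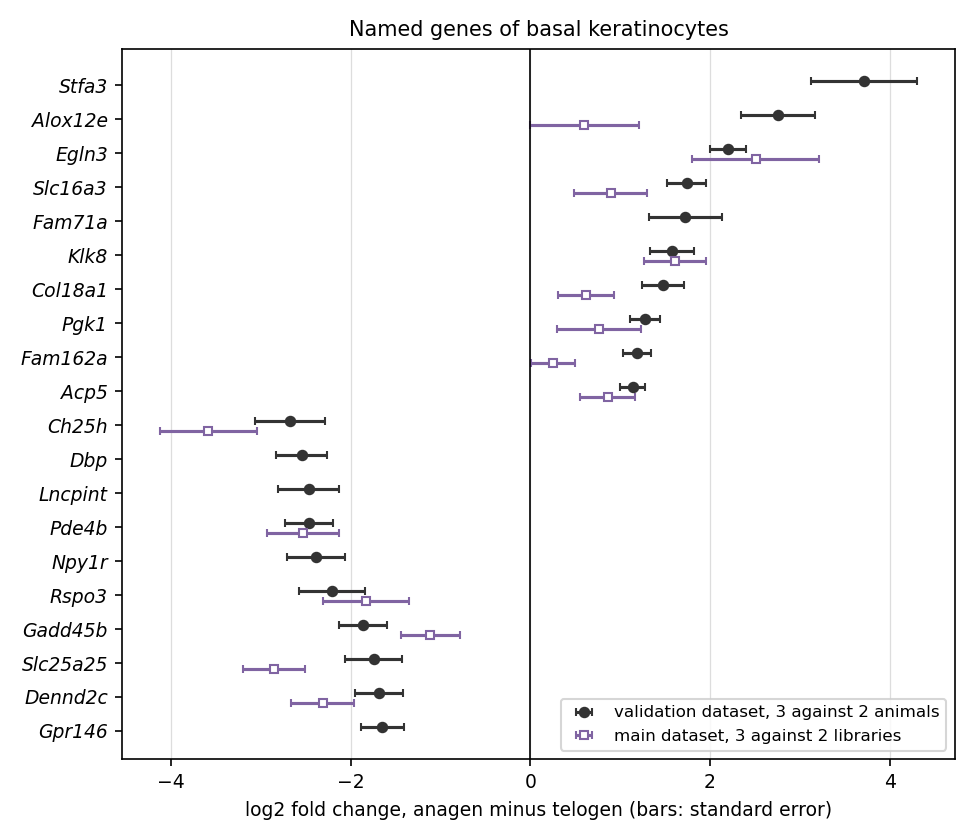
Log2 fold change between stages (horizontal axis, anagen minus telogen, bars are standard errors) of the 20 named genes of basal keratinocytes, in the validation dataset (filled circles) and, where measured, in the main dataset (open squares). Validation values run from 3.72 for Stfa3 to -2.68 for Ch25h.

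Of 10787 genes tested in validation basal keratinocytes, edgeR called 620, of which 345 rose and 275 fell. The 4 Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y were among the rising ones. With the presence of Xist as a covariate 34 genes passed, and without the 2 libraries that lacked Xist 99 passed. Leaving out a library gave 1316, 327 and 354 calls for anagen replicates 1, 2 and 3, and 144, 1378 and 118 for telogen replicates 1, 2 and 3. Without anagen replicate 1 both remaining anagen animals lacked Xist, so sex and stage cannot be told apart there. Within the class a cluster led by Thbs1, Serpinb2 and Fosl1 held 14.6%, 1.82% and 16.5% of the cells of anagen replicates 1 to 3. It held 53.2%, 5.36% and 59.1% of those of telogen replicates 1 to 3. Telogen replicates 2 and 3 came from the same animal. A cycling cluster led by Cenpf, with no marker of the class among its leading genes, held 12.8% of anagen and 2.5% of telogen cells. Without the Fosl1 cluster 401 genes passed. Cell cycle genes rose at anagen in 19 of 30 measured members (24 adjusted over the list alone), including Rrm2, a subunit of ribonucleotide reductase (1.81 ± 0.19), and the cyclin genes Ccnb2 (1.74 ± 0.33), Ccnb1 (1.53 ± 0.26) and Ccna2 (1.51 ± 0.28). The median of the list was 0.99 and camera gave an adjusted p of 1.74e-24, and an adjusted p = 0.274 with an estimated correlation. Glycolysis genes rose in 10 of 17 members (16 adjusted over the list alone), including Tpi1 (1.04 ± 0.18), Gapdh (0.86 ± 0.13) and Pkm (0.85 ± 0.18), with a median of 0.71 (camera adjusted p = 2.97e-11, and adjusted p = 0.297 with an estimated correlation). Of 20 cholesterol synthesis genes 6 rose adjusted over the list alone (median 0.47, camera adjusted p = 0.00278, and adjusted p = 0.549 with an estimated correlation). In main basal keratinocytes neither list passed, with a median of 0.14 for 15 glycolysis genes (camera adjusted p = 0.185) and of -0.01 for 15 cholesterol synthesis genes (adjusted p = 0.748), and no member called over all genes. Hair lineage transcripts were also higher in these cells at anagen, 7 of 9 measured ones by the gene test, such as Krt71 at 16.8 against 0.121 CPM (camera adjusted p = 8.73e-20, and adjusted p = 0.274 with an estimated correlation).

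In the main dataset (5 libraries, 200703 to 893311 UMIs each) edgeR called 174 of 6821 genes in basal keratinocytes, 44 rising and 130 falling. Nr4a1, Atf3 and Dnajb1, which respond early to stimuli or to heat, fell by 1.84 (SE 0.18, 447 against 1587 CPM), 1.52 (SE 0.17) and 1.64 (SE 0.17) on the log2 scale, with adjusted p between 0.00823 and 0.013. Immediate early and heat shock genes fell in 5 of 20 members (10 fell and 2 rose adjusted over the list alone), with a median of -0.65 (camera adjusted p = 1.09e-06, and adjusted p = 0.258 with an estimated correlation). Of 7 complement and chemokine genes Icam1 (-2.31 ± 0.42), Nfkbia (-1.5 ± 0.13) and Cxcl14 (-1.09 ± 0.18) fell, and 6 fell adjusted over the list alone (camera adjusted p = 6.10e-07, and adjusted p = 0.217 with an estimated correlation). Cell cycle genes had a median of 0.58 with none of 30 past the edgeR test, over all genes or adjusted over the list alone (camera adjusted p = 9.19e-06, and adjusted p = 0.161 with an estimated correlation). BMP targets had a median of 0.59, with none of 7 called over all genes and 4 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.00536, and adjusted p = 0.254 with an estimated correlation). In validation basal keratinocytes BMP targets had a median of -0.47 with 1 falling (camera adjusted p = 0.0753). The difference of the differences had an exact permutation p of 0.02 and an adjusted p of 0.42. The haemoglobin genes Hbb-bs (12.2 against 127 CPM), Hba-a1 and Hba-a2 fell (camera adjusted p = 1.02e-08, and adjusted p = 0.161 with an estimated correlation), and 6 of 9 hair lineage transcripts rose (camera adjusted p = 6.49e-13, and adjusted p = 0.171 with an estimated correlation). A cluster led by Serpinb2 and Fosl1 held 8.96% of the anagen and 72.8% of the telogen cells of the class. Without it 10 genes passed. A cluster led by Dkc1 held 19.4% against 0.166% and a cycling cluster led by Cdc20 held 14.7% against 10.3%, and neither had a marker of the class among its leading genes. In clusters held by both stages 5 genes passed. Without main anagen replicate 1 or 2 no gene passed the edgeR test. Without main telogen replicate 2 there were 263 calls. Of the 460 validation calls measured in both datasets, 401 had the same sign (87.2%, exact 95% interval 83.8 to 90.1), against 63.1% of the genes not called. This interval, and those of the other classes, count genes as independent, which they are not, so they may be too narrow. Both datasets called 52, of which 23 rose and 29 fell, against 1.58 and 3.31 for independent lists of these lengths. The rising ones included the hair lineage transcripts Krt25, Krt35, Krt71 and Krtap8-1. Across 6767 genes, which are not independent replicates, the log2 differences had a Pearson r of 0.552. Ch25h (-3.58), Pde4b (-2.53), Slc25a25 (-2.85) and Dennd2c (-2.31) were among the genes called in both, with adjusted p from 0.0154 to 0.0276 in the main dataset, while Egln3 had a log2 difference of 2.51 there and an adjusted p of 0.121.

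In differentiated keratinocytes of the validation dataset (303143 to 4334832 UMIs per animal) Stfa1, a cysteine protease inhibitor, rose from 3.72 ± 0.097 to 115 ± 101 CPM (log2 difference 5.20 ± 0.63, adjusted p = 8.31e-04 by edgeR). Klk8 rose by 3.14 ± 0.37 (87.6 against 10.4 CPM, adjusted p = 7.82e-04), and Krt14, a keratin of the basal layer, by 1.35 ± 0.25 (4284 against 1683 CPM, adjusted p = 0.0095). Cldn4, a tight junction protein, went from 122 ± 48.8 CPM at telogen to 12.5 ± 7.87 CPM at anagen (-2.96 ± 0.33, adjusted p = 7.82e-04). Ovol1, a zinc finger transcription factor, fell by 2.09 (SE 0.24, 85.9 against 359 CPM), and Spry1, an inhibitor of receptor tyrosine kinase signalling, by 2.06 (SE 0.21, 35.9 against 136 CPM), both with an adjusted p of 7.82e-04. The other named rising genes were Fam162a, Egln3, Serpinb6a, Dhx29, Pgk1, Tpi1 and Higd1a, between 1.61 for Fam162a and 1.2 for Higd1a. The other falling ones were Plscr4, Rspo3, Kctd12, Tspan8, Arc, Mlxip and Rfx2, between -2.94 for Plscr4 and -1.68 for Rfx2. Without telogen replicate 3 Arc was -0.50 (adjusted p = 0.68). They came from 37 rising and 96 falling genes that met the rule. Stfa1 lies on chromosome 16 at 36276951 to 36285373, Cldn4 on chromosome 5 at 134945119 to 134946934 and Ovol1 on chromosome 19 at 5549136 to 5560646. Glycolysis genes rose in 10 of 17 members (12 adjusted over the list alone), such as Hk2 (1.29 ± 0.26), Pkm (1.08 ± 0.16) and Ldha (1.04 ± 0.18), with a median of 0.76 (camera adjusted p = 2.37e-15, and adjusted p = 0.274 with an estimated correlation). Cell cycle genes rose in 4 of 21 members (5 rose and 1 fell adjusted over the list alone), namely Birc5, Top2a (2.04 ± 0.52), Ccnd1 (1.07 ± 0.28) and Tyms, with a median of 0.55 (camera adjusted p = 7.04e-04, and adjusted p = 0.274 with an estimated correlation). Hk2 was -0.05 with Xist as a covariate and -0.06 without the libraries that lacked it, and Birc5 was -2.57 under the covariate. Both settings rest on anagen replicate 1, with 11 of these cells, as the only anagen animal. They cannot tell an effect of sex from the values of that animal. Mvd was the member called of 19 cholesterol synthesis genes (2.26 ± 0.56, with 3 rising adjusted over the list alone, camera adjusted p = 0.0109, and adjusted p = 0.628 with an estimated correlation). Hair lineage transcripts were higher in 6 of 7 members (camera adjusted p = 1.02e-14, and adjusted p = 0.274 with an estimated correlation), such as Krt71 at 14.1 CPM against 0.

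Of 9026 genes tested there, edgeR called 371, 161 rising and 210 falling, and DESeq2 165. With the presence of Xist as a covariate 3 genes passed, and without the libraries that lacked it 2 passed. The smallest animal, validation anagen replicate 1, had 11 of these cells. It was also the only validation anagen animal with Xist, so without it sex and stage cannot be told apart. Without it 763 genes passed, and without anagen replicates 2 and 3 and telogen replicates 1, 2 and 3 the counts were 64, 205, 88, 705 and 41. In the main dataset (3 against 3 libraries, 103204 to 867393 UMIs) edgeR called 17 of 3665 genes. Those rising were mostly hair lineage transcripts, with S100a3 at 201 ± 61.2 against 1.69 ± 1.93 CPM, and 7 of 9 members of that list (9 adjusted over the list alone) rose (camera adjusted p = 1.48e-63, and adjusted p = 0.0444 with an estimated correlation). Serpinb2 (-2.08 ± 0.28), the NF-kB inhibitor gene Nfkbia (-1.52 ± 0.22), Myc (-1.87 ± 0.29) and the growth factor gene Areg (-2.96 ± 0.49), singled out after their values were seen, were among the 7 that fell, with adjusted p from 0.0236 to 0.0466. Immediate early genes had a median of -0.34 (4 of 19 fell adjusted over the list alone, none over all genes, camera adjusted p = 3.83e-04, and adjusted p = 0.388 with an estimated correlation). Glycolysis genes had a median of 0.45 (none of 12 called, camera adjusted p = 0.00173, and adjusted p = 0.254 with an estimated correlation). Lipid barrier and cornification genes had a median of -0.67 (none of 8 called over all genes, 1 falling adjusted over the list alone, camera adjusted p = 0.00536, and adjusted p = 0.368 with an estimated correlation). Without main telogen replicate 3 there were 43 calls, and without the others 1 to 6. Restricted to genes at or above the level of all cells, no gene passed edgeR. Of 206 validation calls measured in both datasets, 164 had the same sign (79.6%, exact 95% interval 73.5 to 84.9), against 55.6% of the genes not called. Both called 8 genes, 6 rising and 2 falling, against 0.193 and 0.205 for independent lists. The rising ones included the hair lineage transcripts Krt25, Krt28, Krt71 and Krtap8-1.

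The bulge and outer root sheath class gave the largest count of calls among the validation classes. Fabp5, a fatty acid carrier, rose from 6.17 ± 1.2 to 3930 ± 319 CPM (log2 difference 9.41 ± 0.22, adjusted p = 6.89e-07 by edgeR), and Gjb2, the gap junction protein connexin 26, from 0.925 ± 1.31 to 1038 ± 344 CPM (9.35 ± 0.54, adjusted p = 1.48e-04). Lrat, which esterifies retinol, was at 70.1 ± 10.3 CPM with 0 counts at telogen, at least 118-fold higher against a floor of 3 UMIs over the telogen group (0.596 CPM). Cck, the gene of the peptide cholecystokinin, was at 145 ± 17.6 CPM at telogen with 0 counts at anagen, at least 251-fold lower. Il31ra, a cytokine receptor, had a log2 difference of -4.64 ± 0.51 (7.94 against 218 CPM), and Sncg, gamma synuclein, of -4.97 ± 0.46 (4.52 against 173 CPM). Of the other rising genes, Bpifc, Trf, Dnmt3l, Ttc7b and Rnf223 had 0 counts at telogen and were at least 140, 66.4, 64.1, 41.0 and 35.7-fold higher, Cmah rose by 8.26 ± 0.53, and Wfdc18 went from 0.116 to 70.9 CPM. Of the other falling genes, Grik1, a glutamate receptor subunit, was at least 46.6-fold lower against 0.577 CPM, Fam13a and Fam13c fell by 5.25 (SE 0.60) and 4.74 (SE 0.57), and Aadac (0.370 against 47.0 CPM), the adrenergic receptor gene Adra2a (0.257 against 22.4 CPM), Skint3 (0.557 against 29.7 CPM) and Ccl27b (0.557 against 22.6 CPM) had 3 counts or fewer at anagen. They came from 442 rising and 683 falling genes that met the rule. Fabp5 lies on chromosome 3 at 10012548 to 10016607, Gjb2 on chromosome 14 at 57098600 to 57104702, Cck on chromosome 9 at 121489824 to 121495694 and Il31ra on chromosome 13 at 112519898 to 112594360. Different clusters held the class in each stage. A cluster led by Pthlh, Gja1 and Krt17 held 60.3% of its anagen cells and 0 of 488 telogen cells, while clusters led by Postn, Krt24 and Cd34 and by Fst and Nrtn held 2.53% and 12.2% at anagen against 43.7% and 32.4% at telogen.

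Of 9785 genes tested in this class, edgeR called 2639, 1416 rising and 1223 falling (725642 to 4311181 UMIs per animal). In clusters held by both stages 327 passed. Anagen replicate 1 had 0 and 2 cells in these clusters and was left out there, so both remaining anagen animals lacked Xist. Without telogen replicate 1 there were 899 calls and without anagen replicate 3 there were 1735. Cell cycle genes rose in 28 of 30 members, over all genes and adjusted over the list alone, such as the mitotic kinase gene Cdk1 (55.5 against 0.116 CPM) and Ube2c (7.03 ± 1.11), with a median of 3.50 (camera adjusted p = 6.42e-15, and adjusted p = 0.510 with an estimated correlation). In the main bulge class 5 cell cycle genes had a median of -0.10 with none called (camera adjusted p = 0.983). Cholesterol synthesis genes rose in 14 of 19 members (15 adjusted over the list alone), such as Sqle (3.03 ± 0.27) and Idi1 (2.80 ± 0.36), with a median of 1.75 (camera adjusted p = 5.42e-11, and adjusted p = 0.510 with an estimated correlation). Stem cell quiescence genes fell in 6 of 15 members and rose in 1 (7 and 1 adjusted over the list alone). Fgf18, a growth factor of the resting follicle (-2.69 ± 0.60), the prolactin receptor gene Prlr (-2.62 ± 0.56), Fzd3 (-1.49 ± 0.22) and Foxp1 (-1.47 ± 0.26) fell, and the cyclin gene Ccnd2 rose (1.53 ± 0.24), with a median of -1.0 (camera adjusted p = 0.0382, and adjusted p = 0.543 with an estimated correlation). Foxp1 was 0.07 in clusters held by both stages. In the main bulge class 6 quiescence genes had a median of -0.03 with 1 rising and 1 falling (camera adjusted p = 0.956). Glycolysis genes rose in 9 of 16 and fell in 2 (10 and 2 adjusted over the list alone), with Eno1 at 1.66 ± 0.17 and Bnip3, a mitochondrial membrane protein, at -1.68 ± 0.32 (camera adjusted p = 0.0436, and adjusted p = 0.565 with an estimated correlation). All 4 haemoglobin genes fell, such as Hbb-bs at 34.9 against 589 CPM (camera adjusted p = 0.0474, and adjusted p = 0.549 with an estimated correlation), and without validation telogen replicate 3 the log2 differences of Hbb-bs, Hba-a1, Hba-a2 and Hbb-bt were -0.31, -0.09, 0.05 and 0.86, none past the test. Hair lineage transcripts rose in 6 of 9 (camera adjusted p = 0.00148, and adjusted p = 0.510 with an estimated correlation), with Krt25 at 175 against 0.578 CPM.

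In the main dataset edgeR called 347 of 2796 genes in this class (5 libraries, 76423 to 279415 UMIs each), 156 rising and 191 falling. There a cluster led by Krt6a and Krt17 held 63.6% of the anagen and 0.781% of the telogen cells, and a cluster led by Lhx2 and Gpha2 held 0% and 38.3%. Immediate early and heat shock genes fell in 16 of 18 members, over all genes and adjusted over the list alone, such as Nr4a1 (-3.03 ± 0.26, 164 against 1352 CPM), Atf3 (-2.73 ± 0.27) and Ier3 (-2.58 ± 0.31), with a median of -1.80 (camera adjusted p = 1.94e-17, and adjusted p = 0.161 with an estimated correlation). BMP targets fell in 5 of 7 members (5 fell and 1 rose adjusted over the list alone), including the transcriptional regulators Id3 (-2.74 ± 0.31, 426 against 2937 CPM) and Id1 (-2.61 ± 0.34) and the BMP antagonist gene Grem1 (-3.06 ± 0.67), with a median of -2.29 (camera adjusted p = 0.00102, and adjusted p = 0.254 with an estimated correlation). Without main telogen replicate 2 Grem1 was -1.37 (adjusted p = 0.137). In the validation dataset the 20 immediate early genes had a median of 0.38 with 5 rising (camera adjusted p = 0.13). The difference of the differences for this list had an exact permutation p of 0.03 and an adjusted p of 0.42 over 42 pairs of class and list. In clusters held by both stages the edgeR test called 0 main genes, with anagen replicate 3 left out for having 8 cells there. In the whole class, without anagen replicates 1 and 2, there were 132 and 130 calls. Of 1008 validation calls measured in both datasets, 691 had the same sign (68.6%, exact 95% interval 65.6 to 71.4), against 53.3% of the genes not called. Both datasets called 88 rising and 57 falling genes, against 36.7 and 23.4 for independent lists. Fabp5 (3.71, adjusted p = 0.0352), Gjb2 (4.55, adjusted p = 0.0022) and Fam13a (0 against 126 CPM, adjusted p = 0.0072) were among them.

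In fibroblasts of the validation dataset edgeR called 0 of 9323 genes, with 828 at an unadjusted p under 0.05, and DESeq2 called 37 (169958 to 1471846 UMIs per animal, the smallest with 10 cells). Collagen and collagen processing genes lay higher at anagen as a list, with a median of 0.56 over 27 members, 11 of them rising adjusted over the list alone (camera adjusted p = 1.12e-07, and adjusted p = 0.510 with an estimated correlation). Complement and chemokine genes lay lower, with a median of -1.0 over 23 members, 8 falling adjusted over the list alone (camera adjusted p = 3.90e-10, and adjusted p = 0.348 with an estimated correlation). Interferon response genes had a median of -0.73 over 23 members (camera adjusted p = 1.52e-07, and adjusted p = 0.543 with an estimated correlation). Cell cycle genes had a median of 0.63 over 11 members, with 4 rising adjusted over the list alone (camera adjusted p = 5.16e-04, and adjusted p = 0.348 with an estimated correlation). Wnt targets (16 members, median 0.58, camera adjusted p = 0.0109), BMP targets (9 members, median 0.53, 1 rising adjusted over the list alone, adjusted p = 0.0374) and glycolysis genes (16 members, median 0.37, adjusted p = 0.0415) also passed camera, and had adjusted p of 0.543, 0.549 and 0.543 with an estimated correlation. Of 5 hair lineage transcripts 4 were higher adjusted over the list alone (camera adjusted p = 2.85e-09, and adjusted p = 0.274 with an estimated correlation). A cluster led by the adventitial marker Pi16 held 20 of 50, 0 of 10 and 0 of 20 fibroblasts of anagen replicates 1 to 3 and 37 of 97, 0 of 15 and 40 of 74 of telogen replicates 1 to 3. Without it 8 genes passed edgeR. Anagen replicate 1 was the only anagen animal with Xist, so a test without that replicate cannot tell sex and stage apart. With Xist as a covariate 27 passed, without the libraries that lacked it 194, and without anagen replicate 1 there were 467.

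In main fibroblasts (5 libraries, 57181 to 212667 UMIs each) edgeR called 3 of 1402 genes, all falling and named after their values were seen. Ccl7, a chemokine that attracts monocytes, went from 3656 to 128 CPM (-4.77 ± 0.48, adjusted p = 0.0242), Junb, an immediate early transcription factor, fell by 1.51 (SE 0.20, adjusted p = 0.0446), and AY036118 fell by 3.31 (SE 0.38, adjusted p = 0.0275). Immediate early and heat shock genes fell in 1 of 18 members over all genes and 15 adjusted over the list alone, with a median of -1.2 (camera adjusted p = 2.30e-14, and adjusted p = 0.161 with an estimated correlation). In validation fibroblasts 20 of these genes had a median of 0.14 with none called (camera adjusted p = 0.559). Complement and chemokine genes had a median of -1.19 over 15 members (1 falling, 5 adjusted over the list alone, camera adjusted p = 5.82e-10, and adjusted p = 0.217 with an estimated correlation). Collagen genes had a median of 0.84 over 23 members (5 rising adjusted over the list alone, camera adjusted p = 2.20e-10, and adjusted p = 0.107 with an estimated correlation). Adipogenic genes had a median of -1.2 over 4 members (2 falling adjusted over the list alone, camera adjusted p = 0.00465, and adjusted p = 0.217 with an estimated correlation). The Pi16 cluster held 3 of 34, 1 of 24 and 17 of 26 cells of anagen replicates 1 to 3 and 29 of 56 and 87 of 174 of telogen replicates 1 and 2. Without it 35 genes passed. Without main anagen replicate 3 there were 76 calls and without telogen replicate 2 there were 26, while without anagen replicate 1 or 2 or telogen replicate 1 edgeR called none. Among genes measured in both datasets 62.3% of 1394 had the same sign.

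In macrophages and dendritic cells of the validation dataset edgeR called 0 of 7917 genes, with 760 at an unadjusted p under 0.05, and DESeq2 called 18 (410869 to 1280149 UMIs per animal). Resident macrophage genes, such as those of scavenger receptors, had a median of -0.68 over 16 members, none passing adjusted over the list alone (camera adjusted p = 1.52e-04, and adjusted p = 0.543 with an estimated correlation). A cluster led by the monocyte genes Chil3, Plac8 and Lyz2 held 5 of 59, 7 of 21 and 31 of 72 cells of anagen replicates 1 to 3 and 4 of 56, 0 of 4 and 1 of 44 of telogen replicates 1 to 3. A cluster led by C1qa held 18, 1 and 12 cells of the same anagen replicates and 18, 2 and 15 of the telogen replicates. Cell cycle genes had a median of 1.90 over 26 members, 6 of them rising adjusted over the list alone (camera adjusted p = 1.27e-13, and adjusted p = 0.447 with an estimated correlation), and glycolysis genes a median of 0.44 over 16 members (camera adjusted p = 0.00108, and adjusted p = 0.510 with an estimated correlation). Wnt targets (3 members, median -1.0, 1 falling adjusted over the list alone, camera adjusted p = 0.0349) and haemoglobin genes (3 members, median -1.40, 1 falling adjusted over the list alone, camera adjusted p = 0.00584) lay lower, with adjusted p of 0.543 and 0.518 with an estimated correlation. Of 5 hair lineage transcripts 4 were higher adjusted over the list alone (camera adjusted p = 4.15e-08, and adjusted p = 0.274 with an estimated correlation). Anagen replicate 1 was the only anagen animal with Xist, so a test without that replicate cannot tell sex and stage apart. With Xist as a covariate 5 genes passed edgeR, without the libraries that lacked it 322, and without anagen replicate 1 there were 172.

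In the main dataset (5 libraries, 30166 to 99660 UMIs each) edgeR called 3 of 843 genes in macrophages and dendritic cells, named after their values were seen. Retnla, a gene of alternatively activated macrophages, fell (-2.29 ± 0.28, 3940 ± 1126 against 19375 ± 1879 CPM), as did Cdk2ap2 (-2.51 ± 0.31) and AY036118 (-3.7 ± 0.48), each with an adjusted p of 0.0305. Resident macrophage genes had a median of -0.89 over 8 members (3 falling adjusted over the list alone, camera adjusted p = 0.00973, and adjusted p = 0.238 with an estimated correlation). A cluster led by Ccl8 and C1qb held 5 of 16, 4 of 11 and 6 of 28 cells of anagen replicates 1 to 3. It held 13 of 30 and 35 of 86 cells of telogen replicates 1 and 2. Cell cycle genes (3 members, median 1.74, camera adjusted p = 0.00173), glycolysis genes (7 members, median 0.90, adjusted p = 0.00173) and immediate early genes (17 members, median -0.23, adjusted p = 0.0321) passed camera too, with adjusted p of 0.254, 0.258 and 0.435 with an estimated correlation and 2, 2 and 2 members called adjusted over the list alone. Without anagen replicates 1 or 2 or telogen replicate 1 edgeR called none, without anagen replicate 3 it called 1, and without telogen replicate 2 it called 9. Among 836 genes measured in both datasets 59.9% had the same sign.

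Other lists did not pass. Stress keratin and alarmin genes had a median of 2.75 over 6 members in validation basal keratinocytes, where Stfa1 rose (camera adjusted p = 0.0717), 1.69 over 5 in differentiated keratinocytes, where Krt6a and Stfa1 rose (adjusted p = 0.260), and 1.30 over 3 in the bulge class (adjusted p = 0.484). Krt6a was 0.38 without anagen replicate 3 and -1.45 with Xist as a covariate or without the libraries that lacked it. Lipid barrier and cornification genes had adjusted p of 0.239 in validation basal keratinocytes, where Tgm3 (-0.60 with Xist as a covariate) and Klk7 rose, and 0.854 in differentiated ones, where the glucosylceramide synthase gene Ugcg fell (-1.28 ± 0.28). Interferon response genes had a median of -0.64 in validation basal keratinocytes, where Usp18 fell (camera adjusted p = 0.0634). In the validation bulge class, Wnt targets included falling Dkk3 (-3.10 ± 0.42), Fzd2 and Axin2 (-1.23 ± 0.27) and rising Ccnd1 (2.03 ± 0.30), with a camera adjusted p of 0.279. In clusters held by both stages, where both remaining anagen animals lacked Xist, Fzd2 was 1.08 (adjusted p = 0.0117 by edgeR, a call in the opposite direction) and Dkk3 0.16. BMP targets there included falling Nbl1 (-2.18 ± 0.30) and rising Id4 (1.38 ± 0.21), with an adjusted p of 0.259 in that class. MHC class II genes and phagolysosome genes of macrophages had adjusted p of 0.255 and 0.834 in the validation dataset and 0.721 and 0.560 in the main dataset. Elastic fibre genes of fibroblasts had adjusted p of 0.259 and 0.181, and adipogenic genes of validation fibroblasts 0.327. The lists of angiogenic and endothelial activation genes, fixed for vascular endothelial cells, were not tested.

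Several lists that passed camera in a class of 1 dataset did not pass in the same class of the other. Immediate early and heat shock genes had a median of -0.27 in validation basal keratinocytes, with 2 rising and 2 falling (camera adjusted p = 0.267), of -0.11 in validation differentiated keratinocytes, with 2 falling (adjusted p = 0.601), and of 0.03 in validation macrophages (adjusted p = 0.436). Validation basal keratinocytes had medians of 0.36 for haemoglobin genes (adjusted p = 0.572) and 0.16 for complement and chemokine genes, where Icam1 and Nfkbia fell (adjusted p = 0.771). Main fibroblasts had medians of 0.26 for 6 glycolysis genes (adjusted p = 0.175), 0.16 for 5 interferon response genes (adjusted p = 0.447) and -0.28 for 3 BMP targets (adjusted p = 0.283). Main differentiated keratinocytes had medians of 0.43 for 5 cell cycle genes (adjusted p = 0.627) and -0.16 for 14 cholesterol synthesis genes (adjusted p = 0.607). The main bulge class had medians of 0.57 for 9 glycolysis genes, where Eno1 rose (adjusted p = 0.133), and -0.35 for 3 cholesterol synthesis genes (adjusted p = 0.687).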

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

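The same-sign test for sex and the cluster test for the bulge class were chosen after the results were seen, and the hair transcript test was written before. The melanocyte share, of cells that carry the pigment genes Dct and Pmel, was marked because the difference between stages ran in opposite directions in the 2 datasets with every animal or main library separated, after telogen replicates 2 and 3 were summed as 1 animal. Anagen minus telogen was -0.349 percentage points in the validation dataset and 3.51 in the main dataset, a difference of -3.86 percentage points (exact two-sided permutation p = 0.005, adjusted p = 0.085). Main anagen libraries held 3.04%, 4.67% and 3.20% melanocytes and main telogen libraries 0 of 1174, 5 of 1364 and 0 of 226 cells, while validation animals held 0.430%, 0.671% and 0.730% at anagen and 0.972% and 0.948% at telogen. The telogen libraries of the same animal held 19 of 1452 and 2 of 764 cells, so 1 of them lay above and the other below every anagen animal.

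Ddx3y, a Y-linked RNA helicase gene outside the planned comparisons, was marked as a signal at 39.5 CPM in validation anagen replicate 2 and 40.4 CPM in replicate 3, with 0 counts in the other 10 libraries. Eif2s3y was at 78.2 and 68.1 CPM, Kdm5d at 13.8 and 10.1 CPM and Uty at 16.2 and 12.8 CPM in the same pair of libraries, and Xist at 0.199 and 0.089 CPM. This is the pattern of male tissue, in libraries labelled female. Sex was thus uneven between the validation stages, and it could have produced the calls in basal keratinocytes. Of those calls 87.2% (exact 95% interval 83.8 to 90.1) had the same sign in the main dataset, where every library carried Xist, against 63.1% (61.9 to 64.3) of the genes not called. These values argue against sex as the source of all of these calls. The intervals count genes as independent, which they are not, so they may be too narrow. The comparison cannot tell how many of the calls sex does account for, and it was read for basal keratinocytes alone. Single genes remain open. With Xist as a covariate the stage difference rests on anagen replicate 1 against the telogen animals, with fewer residual degrees of freedom. A call lost there can thus not be laid to sex. Of the named genes and list examples of basal keratinocytes, Tgm3 alone turned sign in that fit, with a log2 difference of -0.60.

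Barcodes that occurred in more than 1 validation library were marked as a signal in data outside the comparisons. There were 2367 such sequences, 218 of them in all 6 libraries, and 5566 of 17037 barcodes (32.7%) were left out as copies, with a median of 963 UMIs against 11326 UMIs for the barcodes kept. With these copies kept, the hair lineage difference was 22.8 percentage points. Before any filter, pairs among anagen replicates 1 and 3 and telogen replicates 1 and 3 shared 1060 to 1210 barcodes. Pairs with anagen or telogen replicate 2 shared 326 to 528. Telogen replicates 2 and 3, summed as 1 animal, thus lie on different sides of that split. What made the copies and the split was not tested.

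The size of the differences in the validation bulge class may come from the different follicle clusters that held it in each stage. In clusters held by both stages the log2 differences of the calls had a median ratio of 0.447 (95% bootstrap interval 0.429 to 0.472) to those in the whole class. There 327 genes passed, and 239 of 1831 measured calls (13.1%) turned sign, with 2 against 2 animals. Anagen replicate 1 had too few cells there, so both anagen animals lacked Xist while both telogen animals carried it. The ratio met the bound set for the cluster explanation, but the test cannot decide. The calls were picked in the whole class, and the clusters left out were those with over 90% of cells of 1 stage, so smaller differences are expected whatever the cause. Of the earlier calls 238 were called again within shared clusters, where sex and stage cannot be told apart. Whether growth state or position in the follicle sets the differences was not tested.

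Hair lineage transcripts such as Krt71 and Krt35 were higher at anagen in nearly every other class, which free RNA of broken hair cells could produce. In anagen libraries their proportions had a median Pearson r of 0.775 with those of the hair lineage cells of the same library, between the value of 0.8 set for free RNA and the value of 0.5 set against it, so the test leaves it open. The median r was 0.849 in the validation dataset and 0.714 in the main dataset, and the median load was 2.27 UMIs per cell at anagen against 0.623 at telogen in the validation dataset and 1.16 against 0.0482 in the main dataset. Doublets with hair cells and follicle cells sorted into other classes were not excluded.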

How the results depend on the processing

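The clusters of both stages, the omission of the Fosl1 or Pi16 cluster, the Xist covariate, the omission of libraries lacking Xist, the shares outside the hair lineage, barcode copies kept, the minimum of 10 cells, the use of 5 main libraries and the list alternatives of the main dataset were chosen after seeing the data. Of 112 alternative values of gene and class counts 52 stayed within 1.5 times the reported value, 32 were lower and 28 higher. Of 2342 values of 191 named genes 1856 kept their direction and side of the threshold, 462 lost the call and 24 turned sign. Of 62 share values 53 stayed the same, and of 144 list values 57 stayed and 87 lost the call. Except where the construction shows it (fewer cells, fewer libraries, fewer or more genes tested), the cause was not tested.

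For validation fibroblasts, with 0 calls, DESeq2 called 37, no low-count filter 100, both datasets in 1 fit 12, barcode copies kept 13, without the Pi16 cluster 8, the Xist covariate 27 and without the libraries lacking Xist 194. For validation macrophages, with 0 calls, these were 18 with DESeq2, 302 with no filter, 2 with both datasets, 5 with the Xist covariate and 322 without the libraries lacking Xist. For validation basal keratinocytes, with 620 calls, no filter gave 1689, the free RNA filter 78, the strict cell filter 214, clustering without called genes 350, thinned cells 19, the class without the Fosl1 cluster 401, the Xist covariate 34 and without the libraries lacking Xist 99. For validation differentiated keratinocytes, with 371 calls, DESeq2 gave 165, no filter 752, the free RNA filter 133, 6 libraries 97, both datasets 62, the strict filter 105, thinned cells 19, copies kept 135, the Xist covariate 3 and without the libraries lacking Xist 2. For the validation bulge class, with 2639 calls, the free RNA filter gave 1577, both datasets 1120, thinned cells 1380 and clusters of both stages 327.

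For main fibroblasts, with 3 calls, DESeq2 gave 35, no filter 223, the replicate block 147 and the class without the Pi16 cluster 35. For main basal keratinocytes, with 174 calls, no filter gave 765, the free RNA filter 23, the replicate block 374, clusters of both stages 5 and the class without the Fosl1 cluster 10. For main differentiated keratinocytes, with 17 calls, DESeq2 gave 41, no filter 354, the free RNA filter 0 and the replicate block 39. For the main bulge class, with 347 calls, no filter gave 677, the replicate block 36 and clusters of both stages 0. For main macrophages, with 3 calls, DESeq2 gave 11, no filter 90 and the replicate block 32. Replicate numbers are not known to pair samples, and the block takes up degrees of freedom. Of 17 classes 2 passed with the strict filter, 5 with clustering without called genes and 0 with copies kept, where the hair lineage share differed by 22.8 percentage points. Of 28 called lists of the validation dataset 0 passed with an estimated correlation and 0 with fry, and of 20 of the main dataset 1 and 8. Same-sign agreement of genes under an adjusted p of 0.01 was 97.7% in basal, 88.1% in differentiated keratinocytes and 79.1% in the bulge class.

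Leaving out 1 library at a time gave 0 to 467 calls in validation fibroblasts, 118 to 1378 in basal keratinocytes, 41 to 763 in differentiated keratinocytes, 899 to 2979 in the bulge class and 0 to 172 in macrophages. In the main dataset it gave 0 to 76 in fibroblasts, 0 to 263 in basal keratinocytes, 1 to 43 in differentiated keratinocytes, 130 to 328 in the bulge class and 0 to 9 in macrophages. The classes with a called share were 0 to 7. The share differences ran from 36.2 to 39.2 percentage points for the hair lineage, -19.8 to -10.4 for differentiated keratinocytes, -1.5 to -1.06 for dermal papilla, -0.211 to 1.03 for T cells, -1.60 to 0.493 for macrophages, -7.70 to -3.09 for the bulge class, -5.52 to -2.16 for fibroblasts, -5.30 to -0.172 for sebocytes and -1.84 to -0.463 for vascular cells. These are means over the 2 datasets, and for sebocytes the validation dataset enters as 0 for lack of a cluster. With all libraries the sebocyte difference was -7.12 in the main dataset and -3.56 as that mean. Where an arm kept 1 animal, it was assumed to vary like the other group. Without validation anagen replicate 1 both remaining anagen animals lacked Xist, so sex and stage cannot be told apart in those tests.

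Turned in sign were Alox12e in basal keratinocytes (-1.80 with clustering without called genes, -0.20 in thinned cells), Tgm3 there (-0.60 and -0.61 with the Xist covariate and without the libraries lacking Xist), and in differentiated keratinocytes, with the same pair of settings, Hk2 (-0.0498, -0.0595) and Krt6a (-1.45, -1.45), with Birc5 (-2.57) and Krt28 (-1.80) under the covariate. In the bulge class Btg2 (-0.11), Hspa8 (-0.0561) and Jun (-0.47) turned with both datasets in 1 fit, and Dkk3 (0.16), Foxp1 (0.0742), Fzd2 (1.08), Hk1 (0.18), Hba-a1 (0.16), Hba-a2 (0.89) and, in the main dataset, Ccnd2 (-0.12) in clusters of both stages. Hba-a1 (0.0314), Hba-a2 (0.0069) and Hbb-bt (0.79) turned with clustering without called genes, Hba-a2 (0.10) in thinned cells, and Hba-a2 and Hbb-bt without telogen replicate 3 (leave-outs from -5.95 to 0.0482 and from -4.02 to 0.858). The bulge share (0.679) and the macrophage share (2.47) turned with the strict filter, and the macrophage share outside the hair lineage (1.47) and without validation anagen replicate 2 (0.0163) or telogen replicate 1 (0.493). The T and innate lymphoid share turned without validation anagen replicate 2 (-0.211). None of these shares had passed.

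No value was obtained, for lack of cells in a library, for the strict filter in fibroblasts, bulge cells and macrophages, for clustering without called genes in fibroblasts, for the 6 libraries and the block in validation macrophages, and for vascular cells. Depth limits how many genes were tested. The smallest main pseudobulk, of macrophages, held 30166 UMIs, and 843 genes were tested there against 7917 in the validation dataset.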

Other observations

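The hypoxia list test and the splits of the libraries were written before their results were seen. In the validation bulge class, members of the interferon response list went both ways. Of the interferon response genes Irf7, a transcription factor of interferon induction (2.71 ± 0.55, 12.2 against 1.63 CPM), and Isg15, a ubiquitin-like protein (2.04 ± 0.49), rose at anagen, while Xaf1 (-2.06 ± 0.46), the immunoproteasome gene Psmb9 (-1.20 ± 0.25), Psmb8 (-1.16 ± 0.35) and Ifitm3 (-1.17 ± 0.20, 176 against 398 CPM) fell, with adjusted p from 0.00619 to 0.0421 by edgeR. The chaperone genes Hsph1 (1.76 ± 0.23), Hspa8 (1.05 ± 0.17) and Hspa1a (1.01 ± 0.22) rose, with adjusted p from 0.00214 to 0.0142, as did Jun and Btg2. With both datasets in 1 fit Hspa8, Jun and Btg2 were -0.0561, -0.47 and -0.11, none past the test, and without telogen replicate 2 Jun and Btg2 were 0.56 and 0.40. In the interferon and the immediate early lists camera gave no call, with adjusted p of 0.327 and 0.13.

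Neutrophils, which carry S100a8 and S100a9, were 16 of 3657 validation cells at anagen and 1 of 3039 at telogen, with no cluster named for them in the main dataset (exact permutation, adjusted p = 0.7). Skeletal muscle cells, which carry Acta1 and Ckm, were 0 and 10 validation cells and 15 and 23 main cells (adjusted p = 0.255, permutation). Upper follicle keratinocytes were 4.64% ± 3.34 (n = 3) and 5.50% ± 0.390 (n = 2) of validation cells and 1.34% ± 0.633 (n = 3) and 2.92% ± 1.81 (n = 3) of main cells (adjusted p = 0.523, permutation). Of the main barcodes 148 at telogen were listed with no replicate, and 36 were listed under 2 replicates.

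A hypothesis was that a response to low oxygen may accompany the higher glycolysis genes of validation basal keratinocytes at anagen, a list that did not pass in the main dataset (median 0.14, camera adjusted p = 0.185). Hypoxia-inducible genes lay higher in the validation dataset (camera two-sided p = 0.0354, and p = 0.105 with an estimated correlation). Of these, 13 of 21 lay above 0, with a median log2 difference of 0.285 (95% bootstrap interval over genes -0.122 to 0.491). They lay outside the lists tested in basal keratinocytes, but P4ha1, P4ha2, Adm and Vegfa belong to the collagen or angiogenic lists. Car9, a carbonic anhydrase (3.84 ± 0.83), the collagen prolyl hydroxylase gene P4ha2 (1.29 ± 0.21) and Egln1 (0.57 ± 0.14) rose, and Bhlhe40 fell (-0.85 ± 0.21). In main cells 6 of 15 genes lay above 0, with a median of -0.205 (-0.525 to 0.502) and a camera p of 0.308 in the other direction, where Ddit4 rose (2.51 ± 0.33) and Bhlhe40 (-2.20 ± 0.19) and Adm (-1.95 ± 0.38), which encodes adrenomedullin, fell. By the rule written beforehand, a median at or below 0 in either dataset counted against the hypothesis, and the main median met it. The bootstrap interval of that median spans 0 and was not part of the rule. By the rule the values thus go against a hypoxia response, with the main estimate uncertain.

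For differentiated keratinocytes the 6 main libraries were also split in every other way. The real grouping called 17 genes and the highest other split 0, so that 1 of 10 splits reached the real count, and the splits are too few to decide.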
